A study of Lepeophtheirus salmonis with 48 samples.

How the data were processed

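Expression was measured on 48 2-colour oligonucleotide arrays of 45220 spots, 1 array per pool of 6 lice, on 12 slides of 4 arrays. Per the labels, total RNA of a pool was amplified and labelled with Cy5, and a reference pool of all conditions was labelled with Cy3. Groups were taken from the sex and feed in the labels. Per the file headers, the scanned images were quantified with ImaGene 8.0.1, and the deposited values used here are the spot intensity and its local background in each channel, with no background subtracted. The authors' deposited value table gives a log2 ratio per array for 13862 probes, and how it was made was not given in the sources used here. Set against the scanner values, each of its columns ran in the Cy5 over Cy3 direction (r from 0.86 to 0.975, slope from 0.906 to 1.06). Column medians lay between -0.224 and 0.0157, so arrays were centred near 0, while the method of centring and any further scaling stay unknown. The table served as an alternative only.

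Spots that the image software marked poor were set missing (2.49% of gene spots, leaving 25.9% of tested probes with at least 1 missing array), and spots marked empty were kept. Signal means were corrected with normexp on the background medians (offset 50), log2 ratios of Cy5 to Cy3 were normalised within each array by loess with control and poor spots at weight 0, and the control spots (1264 positive, 153 negative) and 5671 blank spots were left out. A spot counted as above background when its Cy5 signal mean exceeded the background mean by 2 background SDs. Of 38132 gene probes, 31035 above background on at least 5 of 48 arrays were tested and 7097 dim ones were not. Blank spots passed the same cut on 8.31% of occasions, so a tested probe is not thereby shown to be expressed. Arrays of the same group correlated at -0.113 to 0.727 (median 0.412). Over all pairs of arrays the correlation ran from -0.453 to 0.739, so no 2 arrays were near-copies. The labels state the dyes and the sexes differ widely, so the direction of every ratio was kept as labelled.

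Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, written out to handle missing spots) with 8 group means sharing 1 estimate of the spread. Contrasts were tested 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe was called at an adjusted p below 0.05. A difference over both sexes is the mean of the female and the male difference. The interaction was an F test over the 3 medicated feeds. SE is the moderated standard error, and intervals of differences are 95% intervals from the same fit. Every adjusted p in the text comes from this limma fit unless another test is named. Principal components used the probes measured on all arrays.

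The comparisons, the tests, the rule for named probes and most alternatives were fixed before the data were examined. The rule allowed at most 2 higher and 2 lower called probes without a gene name per comparison, those with the largest change. The probe columns for gene names were empty for all 38132 gene probes, and the reference gene table could not be joined to the probe IDs. The 24 gene lists planned (among them transporters, ligand-gated channels, detoxification enzymes, cuticle, yolk and muscle) were therefore not tested.

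Slide and array position were tested as batches. In F tests added to the group means, 0 of 23011 probes were called for slide and 0 for position. Groups were unevenly spread over positions, with 4 of 6 control female arrays at the third position and 3 arrays of each 1xEMB group at the fourth. The alternatives fixed in advance were no background correction, Aquantile between arrays, no filter on dim probes, the authors' value table, the slide as a fixed or random block, array weights, and each of the 48 pools left out in turn. Chosen after seeing the data were the array position as a block, between-array scaling, poor spots kept, a minimum of 3 measured spots per group, the log2 median Cy5 signal as a covariate, and fits without the 6 arrays of widest ratio spread in the authors' value table or without 9 pools with markers of the other sex above 0.2.

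The fit was tested on simulated data with 200 of 31035 probes changed. For 1xEMB against control over both sexes it called 26% of probes changed 1.5-fold, 86.5% of those changed 2-fold and 96.5% of those changed 3-fold. The shares were 2%, 63% and 95.5% for 1xEMB against control in females, 3.5%, 48% and 95.5% for ivermectin against control in males, and 46.5%, 87.5% and 96.5% for 3xEMB against 1xEMB over both sexes. Noise in this simulation was drawn independently for each probe and array. Probes of an array are not independent of each other, so the shares hold only for such noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.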

Results

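Gene expression was measured in pools of the salmon louse, Lepeophtheirus salmonis, a copepod ectoparasite that feeds on the skin, mucus and blood of salmon. The lice came from Atlantic salmon on control feed or on feed with an avermectin, and were collected as pre-adult I, a mobile stage. Avermectins are macrocyclic lactones that act on glutamate-gated chloride channels of invertebrate nerve and muscle. Emamectin benzoate was fed for 7 days at a nominal dose of 50 µg per kg of fish (1xEMB) or 150 µg per kg (3xEMB). Ivermectin was fed at a nominal 50 µg per kg on 2 occasions in each 7-day period for 4 weeks. The ration was 1.1% of body weight on 1xEMB, 1.2% on 3xEMB and 1.0% on ivermectin, and none is given for control feed. Ration therefore cannot be told apart from drug and dose. Each of the 48 pools held 6 lice of 1 sex, and each of the 8 groups of sex and feed had 6 pools, except control males with 5 and males on 3xEMB with 7. RNA of a pool was labelled with Cy5 and hybridised beside a Cy3 reference made from all conditions, on 12 slides of 4 arrays. All levels below are log2 ratios of the pool to this reference.

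The median Cy5 signal of an array lay between 276 and 612 intensity units over a local background of 98.5 to 202. Between 44.1% and 66.6% of the gene probes of an array stood above background, and the number of arrays per group limits the precision of every value. The labels describe separate pools of lice and do not say whether the pools of a feed came from separate fish or tanks, so p-values measure the spread between pools of lice. The files do not pair the probe IDs with genes, so probes are named by ID, in full at first mention and then without the shared ending _PI416592889. Pools are numbered only to name them.

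Sex was the main axis of variation. The first principal component held 27.4% of the variance of 23011 completely measured probes, and the second held 15.1%. All 24 female pools scored between 11.5 and 63.8 on the first component, and 23 of 24 male pools scored between -57.2 and -21.8. The remaining one, male 3xEMB pool 2, stood between the sexes at -2.26.

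**Figure D1:**
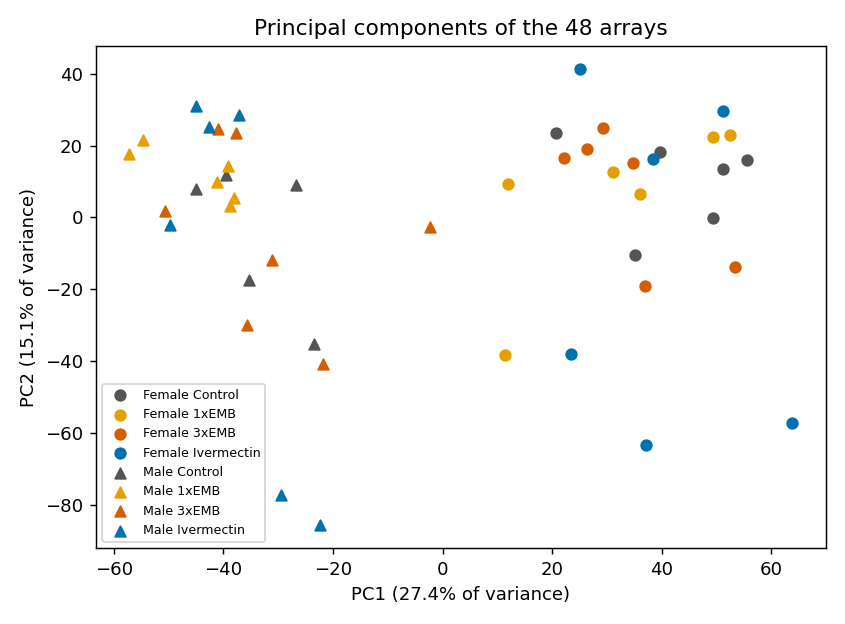
Scores of the 48 arrays on the first (x axis, 27.4% of variance) and second (y axis, 15.1%) principal components of 23011 probes, with circles for female and triangles for male pools and 1 colour per feed. Female pools lie at 11.5 or above on the first component and male pools at -2.26 or below.

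Marker probes of each sex were taken as those at least 16-fold apart between the sexes in the other arrays, 43 to 79 male and 13 to 17 female markers per array. In control females the male markers stood at 0.0195 to 0.188 of the level in male pools (median 0.0374, n = 6). In 8 of the 18 medicated female pools they stood above 0.2, against 0 of 6 control pools (2-sided Fisher's exact test, p = 0.0664). These were 3 of 6 pools on 1xEMB, 3 of 6 on 3xEMB and 2 of 6 on ivermectin, where the highest reached 0.601. Among males, female markers stood above 0.2 in 1 of 24 pools, male 3xEMB pool 2 at 0.362.

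**Figure D2:**
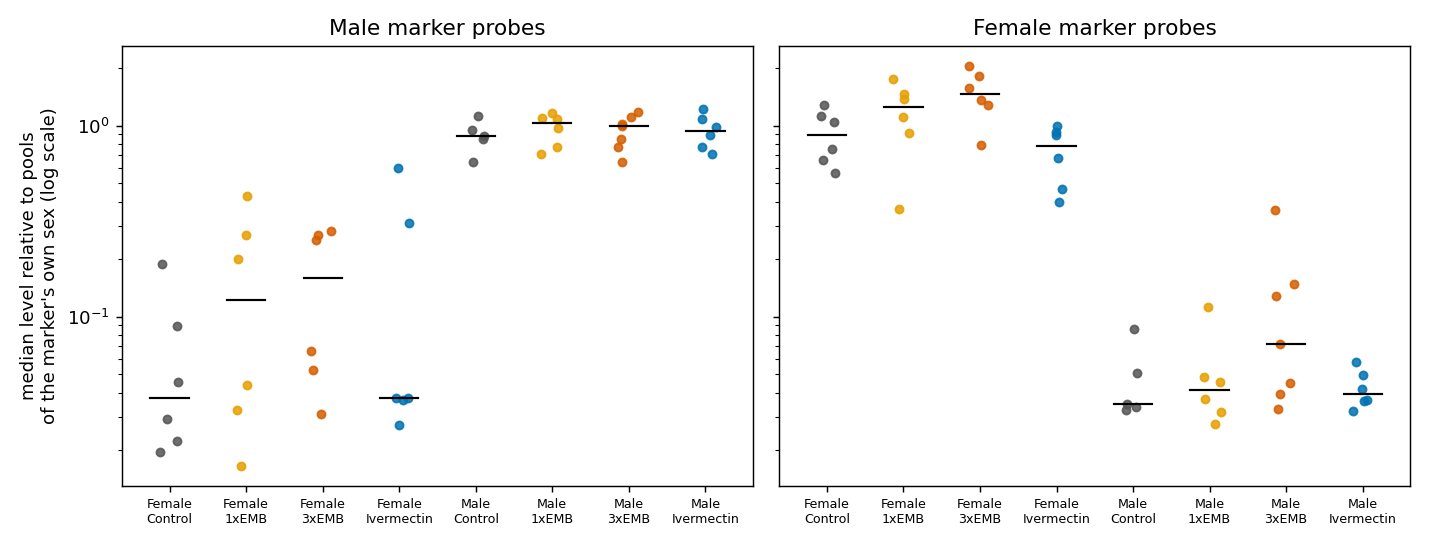
Median level of male marker probes (left) and female marker probes (right) in each pool, on a log scale, relative to the pools of the marker's own sex. Points are pools and lines are group medians, and the female pools reach 0.601 of the male level on ivermectin, 0.430 on 1xEMB, 0.280 on 3xEMB and 0.188 on control feed.

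Males and females on control feed were compared first, since every feed was studied in both sexes. CUST_3630_PI416592889 was higher in males, at -0.25 ± 0.52 in males (SD, n = 5) and -5.82 ± 0.17 in females (SD, n = 6), a log2 difference of 5.57 (SE 0.89, adjusted p = 1.0e-05). CUST_15840_PI416592889 was higher in males by 5.45 (SE 0.92, adjusted p = 3.54e-05), at 0.99 ± 0.58 (n = 4) against -4.46 ± 1.55 (n = 5). CUST_719_PI416592889 was lower in males, at -3.30 ± 2.53 (n = 4) against 1.51 ± 0.90 in females (n = 6), a difference of -4.82 (SE 0.92, adjusted p = 0.000162). Of its 4 measured control male pools, pool 3 stood at 0.48 and the others at -4.37 and below, and with 1 pool left out the difference ran from -6.08, without that pool, to -4.29. CUST_10388_PI416592889 was also lower in males, at -4.69 ± 0.68 (n = 5) against 0.02 ± 0.54 (n = 3), a difference of -4.70 (SE 1.10, adjusted p = 0.00265). In the dimmer sex CUST_3630 was above background on 2 of 6 female arrays, CUST_15840 on 3 of 6 female arrays and CUST_10388 on 2 of 5 male arrays, so these 3 differences rest partly on background. With spots marked poor kept, CUST_15840 differed by 4.71. Each of the 4 probes differed in the same direction in every measured male pool and within every slide and array position that held both sexes. Of 30857 probes tested, 2760 differed, 1775 higher in males and 985 lower, and 1944 of them differed at least 2-fold. The same comparison called 3545 probes on 1xEMB, 2725 on 3xEMB and 3456 on ivermectin. All 4 feeds shared 1338 of these calls, with 970 higher in males and 368 higher in females. Levels of CUST_719 on 1xEMB were -0.34 ± 1.44 in males and -0.56 ± 0.85 in females (SD, n = 6 each). On 3xEMB they were -0.36 ± 1.51 (n = 7) and -0.43 ± 1.71 (n = 6), and on ivermectin -1.60 ± 1.63 (n = 5) and 0.62 ± 1.78 (n = 6). The means of the sexes thus lay close together on both emamectin feeds, but CUST_719 was picked for its difference in control lice. Its male pools also varied on these feeds. On 1xEMB pool 2 stood at -3.03 and the others at -0.71 and above. On 3xEMB pools 6 and 7 stood at -2.55 and -2.22 and the others at -0.34 and above. A loss of the sex difference on these feeds is therefore not shown. With the slide as a block the count in control lice was 2084, and CUST_10388 was no longer called (adjusted p from 2.63e-05 to 0.051 over its alternatives).

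The comparison of 1xEMB with control feed asked how lice respond to the lower emamectin dose. CUST_1745_PI416592889 was lower on 1xEMB in both sexes. In females it stood at -1.23 ± 0.44 against 0.60 ± 0.75 on control feed (SD, n = 6 each), and in males at -0.62 ± 0.57 (n = 6) against 1.81 ± 0.47 (n = 5). Over both sexes it fell by 2.13 on the log2 scale (SE 0.26, 4.37-fold, adjusted p = 1.39e-06). CUST_9724_PI416592889 fell by 1.94 (SE 0.21, 3.83-fold, adjusted p = 5.9e-08), to -0.96 ± 0.58 from 0.74 ± 0.67 in females and to -0.19 ± 0.61 from 1.98 ± 0.41 in males. Both probes were below the control mean of their sex in 12 of 12 pools on 1xEMB. Within slides the difference ran from -2.81 to -1.99 for CUST_1745 and from -2.98 to -1.82 for CUST_9724, over 4 sets of arrays of 1 sex and slide each. Within array positions it ran from -2.71 to -0.17 and from -2.23 to -0.85, over 5 sets each.

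The 2 rising probes named over both sexes were CUST_12095 and CUST_19435. CUST_12095_PI416592889 rose by 1.84 over both sexes (SE 0.46, adjusted p = 0.0235), made up of 3.77 in males and -0.08 in females. CUST_19435_PI416592889 rose by 1.94 (SE 0.54, adjusted p = 0.0398), made up of 3.74 in males and 0.14 in females. Over all 30803 probes limma called 0 differences between the male and the female change on 1xEMB (smallest adjusted p 0.117, and 2298 at an unadjusted p below 0.05 where chance gives 1540.2). Both probes were saturated on 4 of 6 control female and 2 of 6 male 1xEMB arrays, so the sizes given are not exact. Within slides the difference of CUST_12095 kept its direction in 3 of 4 sets of arrays, and 8 of 11 measured pools lay above the control mean of their sex. For CUST_19435 5 of 7 did. Of 30803 probes tested, 943 differed over both sexes, 490 higher and 453 lower, with a median change of 1.55-fold. Only 44 of them changed at least 2-fold. With the slide as a block 4 calls were left, all lower, and CUST_12095 and CUST_19435 were not among them (adjusted p = 0.159 and 0.399), while the differences of the called probes kept their sign at 941 of 941 probes, at a median ratio of 0.912 with an SE 1.15 times as large. The count was 21 with the array position, where the same 2 probes lost their call (adjusted p = 0.122 and 0.0934), and 18 with the Cy5 signal of the array as a covariate. It was 552 without the 9 pools with markers of the other sex above 0.2, 154 with between-array scaling and 1647 without the 6 wide arrays, those with the widest spread of ratios in the authors' deposited values. It ran from 288 without male 1xEMB pool 1 to 1883 without male 1xEMB pool 3, and CUST_12095 and CUST_19435 lost their call in 7 and 15 of 23 fits with 1 pool left out.

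**Figure D3:**
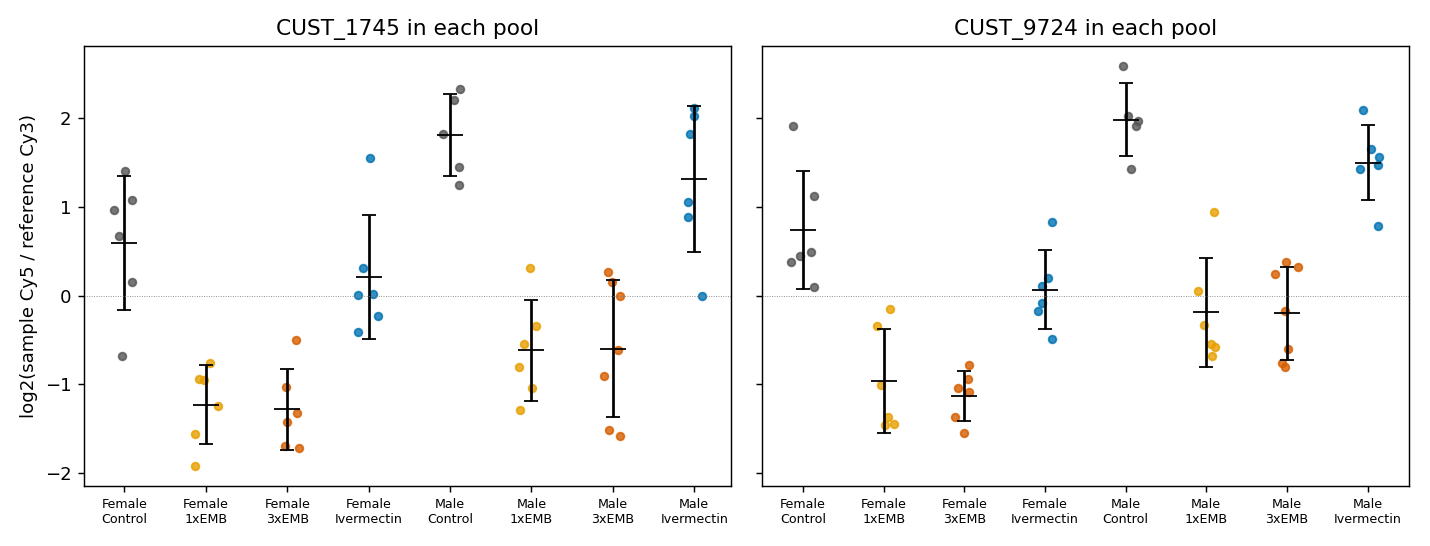
Log2 ratio of sample to reference (y axis) of probes CUST_1745 (left) and CUST_9724 (right) in each pool of the 8 groups of sex and feed (x axis), with the group mean and SD as a bar. On 1xEMB both probes lie below the mean of control pools of the same sex in 12 of 12 pools, and males on control feed average 1.81 and 1.98.

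Within females, 63 of 30888 probes differed on 1xEMB, 45 higher and 18 lower. CUST_22999_PI416592889 rose by 1.67 (SE 0.38, adjusted p = 0.0361) to -0.45 ± 0.55 from -2.11 ± 0.54 (SD, n = 6 each). CUST_23000_PI416592889 rose by 1.66 (SE 0.34, adjusted p = 0.0193) to -0.69 ± 0.45 from -2.35 ± 0.50. Both rose in 6 of 6 pools, and in the 2 slides and the 2 positions that held both feeds. CUST_1745 fell by 1.83 (SE 0.35, adjusted p = 0.0137) and CUST_9724 fell by 1.70 (SE 0.28, adjusted p = 0.00275), each in 6 of 6 pools. Male markers stood above 0.2 in 3 of the 6 female pools on 1xEMB, pools 1, 4 and 5, where CUST_22999 lay at -1.35, -0.06 and 0.09, beside -0.61, -0.06 and -0.69 in pools 2, 3 and 6. The count was 1 with the slide and 0 with the position as a block, where all 4 named probes kept their direction and lost their call (adjusted p from 0.0621 to 0.286), and between-array scaling gave 17 higher and 11 lower calls. It was higher without the 6 wide arrays (313 higher and 154 lower), with array weights (122 and 44), in the authors' deposited values (115 and 45), without background correction (78 and 29) and without the 9 pools with markers of the other sex (81 and 25). With 1 pool left out it ran from 10 without female 1xEMB pool 3 to 139 without female 1xEMB pool 1, and CUST_22999, CUST_23000 and CUST_1745 lost their call in 8, 6 and 2 of 12 such fits.

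Within males, 74 of 30856 probes differed on 1xEMB, 24 higher and 50 lower. CUST_12095 rose by 3.77 (SE 0.64, adjusted p = 0.0038) to -0.09 ± 1.07 (SD, n = 6) from -3.86 ± 1.94 (n = 4). CUST_19435 rose by 3.74 (SE 0.75, adjusted p = 0.0184) to -0.20 ± 1.07 from -3.95 ± 1.85 (n = 4 each). Each of these 2 probes was saturated on 2 of 6 male 1xEMB and 0 of 5 control male arrays, so no fold is given. Spots marked poor left out 1 bright control male pool for each, pool 4 and pool 3 (Cy5 signal 19310 and 18740), and for CUST_19435 also 1xEMB pools 3 and 5 (17330 and 41520). With such spots kept they rose by 3.21 and 3.28 (adjusted p = 0.0121 and 0.00948), and with 1 pool left out by 3.34 to 4.73 and 3.41 to 4.67. CUST_31147_PI416592889 fell by 3.11 (SE 0.61, 8.62-fold, adjusted p = 0.0114) to -3.08 ± 0.88 (n = 6) from 0.03 ± 0.63 (n = 5). CUST_13949_PI416592889 fell by 3.25 (SE 0.71, adjusted p = 0.0297) to -3.25 ± 0.85 (n = 6) from 0.00 ± 0.31, with 3 of 5 control arrays measured. Each of the 4 moved in the same direction in every measured pool on 1xEMB and within every slide or position with both feeds, but for CUST_13949 no slide gave a value. With the slide as a block the count was 5, all lower, and none of the 4 kept its call (adjusted p = 0.0706 for CUST_12095, 0.322 for CUST_19435, 0.456 for CUST_13949 and 0.296 for CUST_31147). The count was 24 with the position, where CUST_13949 lost its call (adjusted p = 0.169), 26 with the Cy5 signal in the model, 173 with array weights (79 higher and 94 lower) and 179 without the 6 wide arrays. It ran from 18 without male control pool 2 to 582 without male 1xEMB pool 3, and CUST_19435, CUST_13949 and CUST_31147 lost their call in 5, 8 and 2 of 11 fits with 1 pool left out.

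The comparison of 3xEMB with control feed asked the same of the higher dose. CUST_1745 fell by 2.15 over both sexes (SE 0.25, 4.42-fold, adjusted p = 4.39e-07), to -1.28 ± 0.46 in females (SD, n = 6) and -0.60 ± 0.77 in males (n = 7). CUST_1746_PI416592889 fell by 2.04 (SE 0.24, adjusted p = 4.39e-07), to -1.53 ± 0.46 from 0.33 ± 0.56 in females and to -0.79 ± 0.64 from 1.44 ± 0.72 in males. CUST_1746 was saturated on 1 of 5 control male arrays, so its size is not exact. Both fell in 13 of 13 pools on 3xEMB, and their differences within slides ran from -2.17 to -1.19 and from -2.21 to -1.28 over 3 sets of arrays. CUST_7190_PI416592889 was called higher (adjusted p = 0.0493), but in females it was above background on 0 of 6 control and 2 of 6 medicated arrays, so no size is given over both sexes. In males it rose by 1.03, from 0.07 ± 0.54 to 1.10 ± 0.50. CUST_12561_PI416592889 was called higher (adjusted p = 0.0493). In females the difference was 1.51, which rests partly on background, as the probe was above it on 1 of 6 control arrays. In males the probe was above background on 0 of 5 control and 2 of 7 medicated arrays, so no size is given in males or over both sexes. In 1 of 3 sets within slides its difference was -0.26. Of 30835 probes tested, 31 differed over both sexes, 8 higher and 23 lower, 15 of them at least 2-fold and all 15 lower. The authors' deposited values of 13862 probes gave 5 higher and 4 lower, and the slide and position blocks left 4 and 5 calls, all lower, without CUST_7190 (adjusted p = 0.788 and 0.0917) and CUST_12561 (0.701 and 0.0731). The count was 18 (13 higher and 5 lower) without the 9 pools with markers of the other sex, 165 (90 and 75) with array weights, 128 (67 and 61) without the 6 wide arrays, 63 without background correction and 66 with between-array scaling. It ran from 5 without male control pool 1 to 44 without female 1xEMB pool 4, and CUST_7190 and CUST_12561 lost their call in 17 and 20 of 24 fits with 1 pool left out.

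Within males, 124 of 30891 probes differed on 3xEMB, 69 higher and 55 lower. CUST_12095 rose by 4.31 (SE 0.70, adjusted p = 0.00191) to 0.45 ± 0.28 from -3.86 ± 1.94 (SD, n = 4 each), and was saturated on 4 of the 7 arrays of 3xEMB males, so no fold is given. CUST_12096_PI416592889 rose by 4.14 (SE 0.76, adjusted p = 0.00475) to 0.29 ± 1.06 (n = 5) from -3.86 ± 1.96 (n = 4), with 2 of the 7 medicated arrays saturated. For CUST_12095 spots marked poor left out control male pool 4 (Cy5 signal 19310, where pool 3 had 21510 and the other 3 had 1200 to 1631) and 3xEMB male pools 4, 6 and 7 (50510, 14190 and 13440, where the measured pools had 40870 to 44340). With such spots kept the rises of CUST_12095 and CUST_12096 were 3.18 and 3.24 (adjusted p = 0.0102 and 0.0172), and with 1 pool left out 3.88 to 5.27 and 3.68 to 5.10. CUST_1745 fell by 2.41 (SE 0.36, adjusted p = 0.000335) and CUST_1746, saturated on 1 of 5 control male arrays, fell by 2.22 (SE 0.34, adjusted p = 0.000425), each in 7 of 7 pools. Within positions all 4 kept their direction, while no slide held measured spots of CUST_12095 or CUST_12096 in both groups. The differences of CUST_12095 within positions, 4.73 and 5.42, used only control male pools 1, 2 and 5, those of low signal. Bright control pool 3 shared its position with no 3xEMB male, and bright pool 4 was left out as poor. These 2 values therefore say nothing of the bright control pools. The slide as a block left 8 calls, all lower, with CUST_1745 and CUST_1746 kept and CUST_12095 (adjusted p = 0.22) and CUST_12096 (0.118) lost. The authors' deposited values gave 61 higher and 20 lower calls, array weights 219 and 132, between-array scaling 130 and 92, and the fit without the 6 wide arrays 124 and 110. With 1 pool left out counts ran from 37 without male control pool 5 to 164 without male control pool 3.

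Within females, 7 of 30899 probes differed on 3xEMB, 2 higher and 5 lower. CUST_9724 fell by 1.87 (SE 0.28, 3.66-fold, adjusted p = 0.00101) to -1.13 ± 0.28 (SD, n = 6), and CUST_1745 fell by 1.88 (SE 0.35, adjusted p = 0.0223). CUST_10787_PI416592889 rose by 1.60 (SE 0.29, adjusted p = 0.0139) to 1.37 ± 0.78 from -0.23 ± 0.46. It was above background on 2 of 6 control and 6 of 6 medicated arrays, so this size rests partly on background. CUST_12561 rose by 1.51 (SE 0.30, adjusted p = 0.0303) to 1.5 ± 0.66 from -0.01 ± 0.52. It was above background on 1 of 6 control arrays, so this size also rests partly on background. The 4 probes moved in the same direction in 6 of 6 pools, and in the 2 slides and 2 positions that held both feeds. Calls were 0 higher and 4 lower without the background correction, where all 7 probes kept their sign, and 0 and 3 in the authors' deposited values, which held 3 of the 7. They were 25 higher and 6 lower without the 9 pools with markers of the other sex, 53 and 16 without the 6 wide arrays and 7 and 7 with array weights. The slide block left 0 calls (adjusted p of the named probes 0.301 to 0.894) and the position block left CUST_9724. Counts ran from 1 without female control pool 3 to 17 without female 3xEMB pool 6, CUST_10787, CUST_12561 and CUST_1745 lost their call in 3, 9 and 7 of 12 fits with 1 pool left out, and 3 of the 6 medicated pools had male markers above 0.2.

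In lice from fish on ivermectin limma called 3 of 30830 probes against control lice over both sexes, with 3159 at an unadjusted p below 0.05 where chance gives 1541.5. CUST_28461_PI416592889 was higher by 0.71 (SE 0.13, adjusted p = 0.0379), in 12 of 12 pools, but was above background on 1 of 6 arrays of ivermectin females, 2 of 6 of ivermectin males and 1 array of each control group, so this size rests on background and no fold is given. CUST_15124_PI416592889 was lower by 0.61 (SE 0.12, adjusted p = 0.0379), in 12 of 12 pools, and was above background on 2 of 5 control male arrays and no other array compared, so the same holds for it. CUST_19465_PI416592889 had a difference of -1.48 (SE 0.25, adjusted p = 0.0379), which came from 1 measured array of ivermectin females at -3.27 and 2 control female arrays at -0.33 ± 0.07, with 1 ivermectin and 2 control female arrays saturated. In males this probe was saturated on all 5 control and all 6 ivermectin arrays, and no difference is given for them. Within females limma called 2 of 30901 probes, with 2195 at an unadjusted p below 0.05 where chance gives 1545.1. One was CUST_19465 (adjusted p = 0.00315), which rests on that 1 array, so its size is not given, and the other was CUST_21134_PI416592889 at 1.72 (SE 0.25, adjusted p = 0.00315; 1.01 ± 0.07 on 2 measured ivermectin arrays, -0.71 ± 0.27 on 6 control arrays). The other 4 ivermectin spots of CUST_21134 were above background but marked poor, and with them kept its difference was 0.65 (SE 0.35, adjusted p = 0.678). Within males limma called 0 of 30876 probes, with 1477 at an unadjusted p below 0.05 where chance gives 1543.8. With spots marked poor kept in, neither the female nor the joint comparison called a probe, and the difference of CUST_19465 over both sexes turned to 0.039 (adjusted p = 0.976). The joint count was 0 in 16 of 48 fits with 1 pool left out. In such fits CUST_28461 lost its call in 13 of 23, CUST_15124 in 19 of 23, CUST_19465 over both sexes in 14 of 22 and CUST_21134 in 2 of 12. Of 13 alternatives CUST_28461 and CUST_15124 lost their call in 10 each, and the slide block left 0 calls in either comparison.

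**Figure D4:**
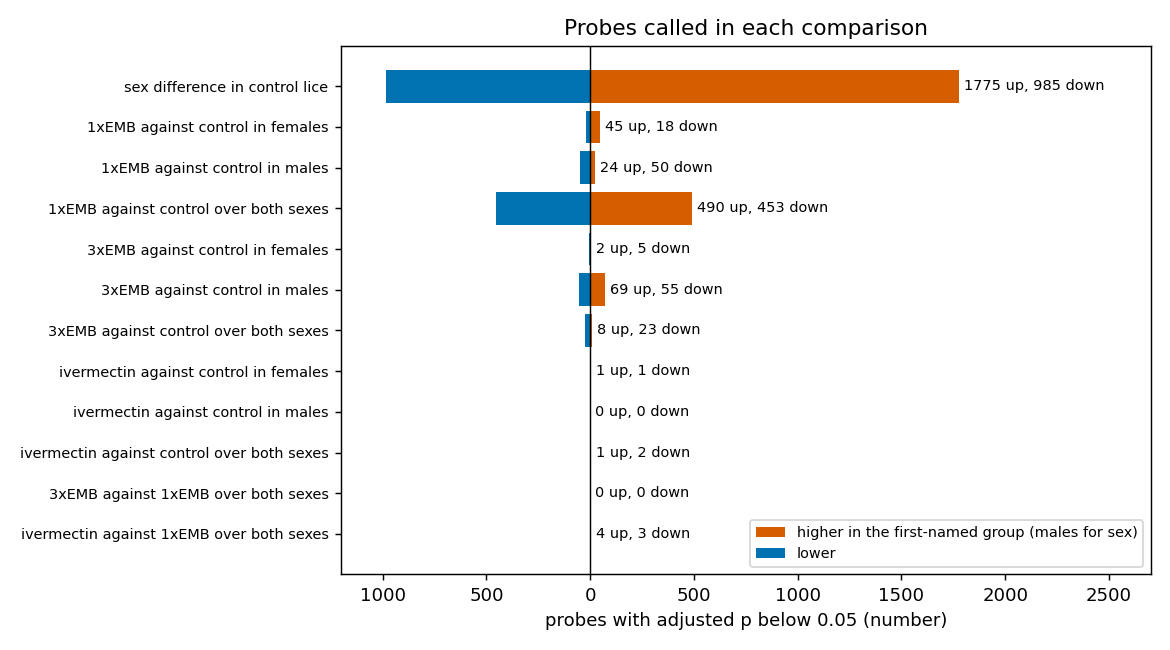
Number of probes past an adjusted p of 0.05 (x axis) in each comparison (y axis), with those higher in the first-named group to the right and those lower to the left. The sex difference called 2760 probes, 1xEMB over both sexes 943, 3xEMB 31 and ivermectin 3.

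Whether the feeds acted differently in males and females was tested over all 3 medicated feeds together and for each. The joint limma test called 0 of 30771 probes, with 1886 at an unadjusted p below 0.05 where chance gives 1538.6. For 3xEMB alone, 7 probes differed, and at all 7 the change was higher in males. CUST_12095 differed by 5.06 (SE 0.96, adjusted p = 0.0387), with -0.75 in females and 4.31 in males, but it was saturated on 4 of 6 control female, 3 of 6 female 3xEMB and 4 of 7 male 3xEMB arrays, so this size is not exact. CUST_27006_PI416592889 differed by 4.19 (SE 0.81, adjusted p = 0.0387), at 0.18 ± 0.57 (SD, n = 7) against -2.83 ± 1.90 (n = 5) in males and -0.39 ± 0.97 against 0.80 ± 0.73 (n = 6 each) in females. For 1xEMB and ivermectin alone limma called 0 probes, with 2298 and 772 at an unadjusted p below 0.05. Across probes, the female and male changes correlated at r = 0.166 for 1xEMB, 0.0191 for 3xEMB and 0.334 for ivermectin, while 100 random relabellings reached 0.475, 0.482 and 0.428. As high a value came from 18, 45 and 2 of the 100 relabellings, and probes are not independent replicates. The joint count was 9 with array weights, 336 without the 6 wide arrays and 58 without the 9 pools with markers of the other sex. Single pools moved it as far as 116, without female ivermectin pool 5.

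The higher dose was set against the lower one over both sexes. Levels of CUST_1745 on 3xEMB and 1xEMB were -1.28 ± 0.46 and -1.23 ± 0.44 in females (SD, n = 6 each) and -0.60 ± 0.77 (n = 7) and -0.62 ± 0.57 (n = 6) in males. No probe of 30856 was called by limma, with 2664 at an unadjusted p below 0.05 where chance gives 1542.8, and none within either sex (930 in females and 2703 in males). For 78.4% of the probes the interval of the difference lay within 1.5-fold either way, and for 97.4% within 2-fold. At the probes called on 1xEMB the log2 change on 3xEMB was a median of 0.483 of that on 1xEMB, but these were picked on the 1xEMB arrays. Without background correction 4 probes differed, and 1 without female 1xEMB pool 6.

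The emamectin doses shared 14 calls over both sexes, 4 higher and 10 lower. Unchanged groups simulated against the same controls shared 0. Independent lists of these sizes, which leave out the shared controls, would share 0.127 and 0.338. The simulation and such lists treat probes as independent of each other, which probes of an array are not. Neither therefore bounds what chance could share. With separate sets of control pools for each dose, in 20 random splits, 1xEMB had a mean of 85.3 and 3xEMB of 12.2 calls, and the doses shared 2 to 5 (mean 3.28) where independent lists would share 0.00905. CUST_1745 and CUST_9724 were called lower on both doses in 20 of 20 of these splits, with the sets of controls either way round, and CUST_1746 in 19. Across probes the 2 differences from control correlated at r = 0.71, and both used the same control pools. Unchanged groups simulated against shared controls gave r = 0.53, and separate sets of control pools for each dose gave 0.40 in the data. The simulated probes were again independent, so this r shows the part due to shared controls and not the spread by chance. The covariance was 0.0473 against a simulated 0.0191, a difference of 0.0282. For 1xEMB and ivermectin the correlation was 0.57 (simulated 0.53, separate controls 0.27), with a covariance difference of 0.0169 and 0 shared calls. For 3xEMB and ivermectin it was 0.57 (simulated 0.54, separate controls 0.23), with a covariance difference of 0.0115 and 0 shared calls.

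Ivermectin and 1xEMB had the same nominal dose of 50 µg per kg but different feeding schedules and rations (1.0% and 1.1% of body weight). Emamectin differs from avermectin by a methylamino group in place of a hydroxyl on the outer sugar, and ivermectin by 1 reduced double bond. CUST_1745 was higher on ivermectin than on 1xEMB by 1.69 (SE 0.25, 3.21-fold, adjusted p = 0.00023), at 0.21 ± 0.70 in females and 1.31 ± 0.83 in males (SD, n = 6 each). CUST_1746 was higher by 1.59 (SE 0.24, adjusted p = 0.00023), and both were higher in 12 of 12 ivermectin pools and within each of 7 sex-by-slide and 6 sex-by-position sets of arrays. CUST_14635_PI416592889 was lower on ivermectin by 0.90 (difference -0.90, SE 0.18, adjusted p = 0.0304), with -1.44 in females and -0.37 in males. CUST_17328_PI416592889 differed by -0.90 (SE 0.18, adjusted p = 0.0304), with -1.12 in females and -0.68 in males. Both kept their direction within every slide and in 5 of 6 position sets, and were lower in 11 and 12 of 12 ivermectin pools. Of 30844 probes, 7 differed, 4 higher and 3 lower on ivermectin. For the rest a difference was not shown, and the interval lay within 1.5-fold for 71.1% and within 2-fold for 96.0% of all probes. The authors' deposited values gave 9 higher and 29 lower calls, the fit without the 9 pools with markers of the other sex 5 and 25, the fit without the 6 wide arrays 7 and 15, the position block 4 and 19, and no background correction 9 and 12. Between-array scaling, array weights and the slide block gave 3 higher and 0 lower, and CUST_14635 and CUST_17328 lost their call with the slide (adjusted p = 0.0575 and 0.105) and the position (0.0599 each) as a block, where CUST_1745 and CUST_1746 kept theirs. With 1 pool left out counts ran from 3, without male ivermectin pool 1 among others, to 100 without female 1xEMB pool 4, and CUST_14635 and CUST_17328 lost their call in 9 and 8 of 24 such fits.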

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

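Every test of the sex markers described here was chosen only after the result was seen. A sample is listed when its gap to the nearest other sample of its group, over the range of the group, passed Dixon's critical value. This held in 14 of 112 groups of values tested, where chance gives about 1 in 20.

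Control males stood out at several named probes. CUST_719_PI416592889 reached 0.48 in male control pool 3, while the 3 other measured control males lay at -4.37 and below. In the same pool CUST_10388 stood at -3.50 (the others at -4.79 and below) and CUST_12095_PI416592889 at -0.97 (the 3 others measured at -4.49 and below). CUST_19435_PI416592889 stood at -1.17 in male control pool 4, with the 3 others measured at -4.77 and below. The unmeasured pool, whose spot was marked poor, was also bright at these last 2 probes and at CUST_719: Cy5 signal was 19310 for CUST_12095 and 4348 for CUST_719 in pool 4 and 18740 for CUST_19435 in pool 3, so pools 3 and 4 stood above the other 3 at all 3 probes. In 1xEMB males pool 2 was the lowest measured at CUST_12095, CUST_19435 and CUST_719 (-2.03, -1.77 and -3.03). In 3xEMB males pools 6 and 7 had the lowest Cy5 signal at each. These 3 probes thus varied together between male pools and are not separate results. Among medicated pools, CUST_12096_PI416592889 was at -1.58 in male 3xEMB pool 6 (the 4 others measured at 0.49 and above, while the unmeasured pool 7 had a Cy5 signal of 6219 beside 7214 in pool 6), CUST_7190 at 0.81 in female 3xEMB pool 1 (the others at -0.32 and below) and CUST_1745 at 1.55 in female ivermectin pool 3 (the others at 0.31 and below). CUST_28461 was at -1.26 in female control pool 3, with the others at -0.14 and above.

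Array measures of single pools stood apart as well. The share of probes above background was 60.2% in female control pool 2 (the others at 51.3% and below) and 65.0% in female 3xEMB pool 2 (the others at 51.7% and below). Each was the only array of its group at the first array position. Arrays there had 60.1% to 66.6% of probes above background, and arrays at the other positions at most 57.8%. These 2 values thus went with array position and do not set the pools apart. Median Cy5 signal was 459.9 in male control pool 4, with the others at 389.5 and below. Poor spots numbered 274 in male 3xEMB pool 2, with the others at 853 and above. In that pool female markers also stood at 0.362 of the female level (the others at 0.148 and below), and in male 1xEMB pool 5 at 0.112 (the others at 0.0486 and below).

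Male minus female changes on 3xEMB that passed limma over all probes were 4.19 for CUST_27006 and 5.06 for CUST_12095, the latter with saturated spots in both sexes. Male minus female values among the named probes were 3.85 for CUST_12095 and 3.61 for CUST_19435 on 1xEMB, but these probes had been picked on the same arrays, 4 of 6 control female arrays were saturated, and over all probes limma called 0 such differences (smallest adjusted p 0.117). The value of CUST_12561 on 3xEMB was -1.13, with 0 of 5 control male and 2 of 7 male 3xEMB arrays above background, so no difference between the sexes is read from it. CUST_19465 on ivermectin had a value of 2.91, which rests on 1 measured array of ivermectin females and on saturated male spots.

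Male marker probes were bright, above 0.2, in 8 of 18 medicated female pools and in 0 of 6 control pools. Near this cut, female 1xEMB pool 1 stood at 0.202 and female control pool 2 at 0.188. Among the 8, female ivermectin pools 2 and 5 and female 1xEMB pool 4 were also arrays of widest ratio spread in the authors' values. A male pool under a female label is argued against, because the highest female pool reached 0.601 of the male level, below the lowest male pool at 0.643. The margin was narrow, as the quartiles of these 2 pools overlapped (0.25 to 0.761 and 0.516 to 1.28). Female markers stood at 0.365 to 1.57 of the female level in the 8 pools, and at 0.674 in the highest, female ivermectin pool 5. The lowest, female 1xEMB pool 4 (0.365) and female ivermectin pool 2 (0.398), lay near male 3xEMB pool 2 (0.362). Male lice within female pools may account for part of the signal and stay open. In 2 of the 8 pools male marker levels spread more widely than in any male pool (log2 interquartile range up to 3.04 against 1.92). A single admixed share would not give this, and the other 6 did not show it. Female control pools 2 and 5, below 0.2, had ranges of 2.86 and 3.05, and the other control female pools 0.65 to 1.10. A wide spread was thus not particular to the bright pools and cannot decide. An effect of medicated feed also stays open, since the log2 marker levels of medicated and control female pools were not shown to differ (exact permutation p = 0.1901, 2-sided, 6 against 18 pools). Development within the pre-adult stage was not tested.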

How the results depend on the processing

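The position block, between-array scaling, poor spots kept, the minimum of 3 measured spots, the fits without arrays of wide ratio spread in the authors' values or without pools with markers of the other sex, and the Cy5 covariate were chosen after seeing the data. The sex difference stayed at 2084 to 3361 calls under every alternative run. Aquantile moved nothing, since it leaves log ratios as they are, and the slide as a random block (consensus correlation -0.011) kept every count within 1.5 times. Causes of the moves below were not tested, except that the minimum of 3 spots removed both probes called on ivermectin in females. CUST_1745 over both sexes on 1xEMB, on 3xEMB and between ivermectin and 1xEMB, and CUST_9724 on 1xEMB, kept direction and call under all 14 alternatives. Of the 37 named results, the slide block kept 11 calls and lost 26, the position block 21 and 16. Only CUST_19465 on ivermectin over both sexes reversed, to 0.039 with poor spots kept (adjusted p 0.976, and 0.0257 to 0.988 over its alternatives). The planned gene list tests were not run for lack of gene names. Signal over background limits dim probes, as 51.2% of gene probes stood above it on the median array. No paired analysis was possible because pool numbers are names in order of deposit and pair nothing across groups.

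Without background correction the counts were 107 for 1xEMB in females, 4 and 63 for 3xEMB in females and over both sexes, 0 for ivermectin over both sexes, 4 for 3xEMB against 1xEMB and 21 for ivermectin against 1xEMB. Without the dim filter ivermectin over both sexes gave 0. The authors' values gave 160 for 1xEMB in females, 3, 81 and 9 for 3xEMB in females, males and both, 0 and 0 for ivermectin in females and both, and 38 for ivermectin against 1xEMB. The slide block gave 1, 5 and 4 for 1xEMB in females, males and both, 0, 8 and 4 for 3xEMB, 0 and 0 for ivermectin in females and both, and 3 for ivermectin against 1xEMB. Array weights gave 166 and 173 for 1xEMB in females and males, 14, 351 and 165 for 3xEMB in females, males and both, 0 for ivermectin over both sexes, 9 for the interaction and 3 for ivermectin against 1xEMB. The position block gave 0, 24 and 21 for 1xEMB in females, males and both, 1 and 5 for 3xEMB in females and both, 1 for ivermectin over both sexes and 23 for ivermectin against 1xEMB. Between-array scaling gave 28, 46 and 154 for 1xEMB, 222 and 66 for 3xEMB in males and both, 1 and 0 for ivermectin in females and both, and 3 for ivermectin against 1xEMB. Poor spots kept, and the minimum of 3 spots, each gave 0 and 0 for ivermectin in females and both. Without the 6 wide arrays the counts were 467, 179 and 1647 for 1xEMB, 69, 234 and 128 for 3xEMB, 1 and 0 for ivermectin in females and both, 336 for the interaction and 22 for ivermectin against 1xEMB. Without the 9 pools with markers of the other sex they were 106 and 552 for 1xEMB in females and both, 31 and 18 for 3xEMB in females and both, 58 for the interaction and 30 for ivermectin against 1xEMB. The Cy5 covariate gave 36, 26 and 18 for 1xEMB and 5 for ivermectin over both sexes. All other counts stayed within 1.5 times.

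Leaving out 1 pool at a time gave 2276 to 2862 calls for the sex difference. Pools that moved a count by more than 1.5 times follow, each by group and number. For 1xEMB in females it gave 10 to 139, with 139, 10, 119, 27 and 19 without female 1xEMB 1, 3, 4, 5 and 6, 24, 32, 104 and 27 without female control 3, 4, 5 and 6, 120 and 95 without female ivermectin 3 and 5, 97 without male 1xEMB 3. For 1xEMB in males the counts were 18 to 582, with 23, 46, 582, 46 and 33 without male 1xEMB 1, 2, 3, 4 and 5, 43, 18, 115 and 25 without male control 1, 2, 4 and 5. For 1xEMB over both sexes the counts were 288 to 1883, with 473, 470 and 599 without female 1xEMB 3, 5 and 6, 583 and 457 without female control 1 and 2, 288, 390, 1883 and 345 without male 1xEMB 1, 2, 3 and 5, 476, 364 and 601 without male control 2, 3 and 5. In 3xEMB females they were 1 to 17, with 11 without female 1xEMB 4, 1, 1 and 17 without female 3xEMB 3, 5 and 6, 4, 1 and 3 without female control 2, 3 and 4. In 3xEMB males they were 37 to 164, with 59 without male 3xEMB 1, 38, 45 and 37 without male control 1, 2 and 5. For 3xEMB over both sexes they were 5 to 44, with 16, 10 and 11 without female 3xEMB 1, 2 and 5, 6 and 7 without female control 2 and 5, 11 and 9 without male 3xEMB 1 and 7, 5, 11 and 15 without male control 1, 2 and 3. On ivermectin, females had 1 to 3, with 1, 1 and 1 without female ivermectin 2, 3 and 5. On ivermectin, males had 0 to 1, with 1 and 1 without male control 1 and 4. On ivermectin, both sexes together had 0 to 4, with 0 without female 3xEMB 6, female control 2, 4 and 5, female ivermectin 2 and 4, male 1xEMB 1, male 3xEMB 2, 4 and 7, male control 2, 4 and 5 and male ivermectin 1, 3 and 5, 1 without female control 1, female ivermectin 3 and male control 3. The interaction had 0 to 116, with 74 without female 1xEMB 4, 1 without female 3xEMB 1, 116 without female ivermectin 5, 1 without male 3xEMB 2, 79 and 22 without male control 3 and 4, 12 without male ivermectin 5. The comparison of doses had 0 to 1, with 1 without female 1xEMB 6. Ivermectin against 1xEMB had 3 to 100, with 3 and 100 without female 1xEMB 3 and 4, 30 without female 3xEMB 3, 30, 3, 13, 43 and 17 without female ivermectin 1, 2, 3, 4 and 5, 3, 3 and 41 without male 1xEMB 1, 2 and 3, 3, 11, 30, 65 and 4 without male ivermectin 1, 3, 4, 5 and 6.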

Other observations

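In this part only the test of probes picked in the other sex was chosen before its result was seen; the tests by array position and Cy5 signal, those of the wide arrays and the regroupings of the pools were chosen after.

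The change on 1xEMB was followed from one sex to the other. The 500 probes with the smallest limma p on 1xEMB in females were scored in males, in the direction they took in females. In males on 1xEMB they averaged 0.31 ± 0.30 (log2, SD, n = 6, exact permutation p = 0.0887 against 5 control pools). In males on 3xEMB the same probes averaged 0.05 ± 0.19 (n = 7, exact p = 0.648). The 500 probes picked on 1xEMB in males averaged 0.11 ± 0.18 in females on 1xEMB (n = 6, exact p = 0.405). No score passed a p of 0.05, so a shared response beyond single probes such as CUST_1745 was not shown by this measure.

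More probes were called at 1xEMB than at 3xEMB over both sexes, 943 against 31. Within females the counts were 63 against 7, but within males 74 against 124. Over both sexes the order was lost with the slide as a block (4 and 4) and turned with the Cy5 signal as a covariate (18 against 41). It held in the other alternatives. Array position as a block left the log2 differences of the 943 probes at a median ratio of 0.932 (quartiles 0.857 and 1.01). Their median size was 0.592, and 0.629 before, so position did not account for most of the size of these differences. The calls dropped to 21 while the SE rose 1.12 times, and 3xEMB had 5 calls with this block. Position stays open as a part of the gap in calls, since the 943 probes were picked without the block. The Cy5 signal was brighter on 1xEMB arrays (group means 482 in males and 466 in females, against 397 and 416 on control feed and 429 and 431 on 3xEMB). Among 1xEMB males it was 612, 590 and 555 in pools 1, 2 and 5, and 318, 408 and 410 in pools 3, 4 and 6. Without pool 1, 2 or 5 the 943 calls fell to 288, 390 and 345, and without pool 3 they rose to 1883. Without pool 4 or 6 they stayed within 1.5 times. The Cy5 signal may account for part of the gap and stays open. As a covariate it lowered the differences to a median ratio of 0.774 (quartiles 0.701 and 0.852, median size 0.483). The SE was 0.157, and 0.161 before. The covariate left 18 calls, below the 41 at 3xEMB in the same fit. A stronger response to the lower dose also stays open, because probes picked in the other sex moved further on 1xEMB than on 3xEMB by 0.26 in males (exact permutation p = 0.0798) and 0.07 in females (exact p = 0.5844), neither past the threshold. In the direct comparison of the doses no probe was called.

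In the authors' deposited values log ratios were spread most widely on 6 arrays: male ivermectin pools 1 and 6, female ivermectin pools 2, 5 and 6, and female 1xEMB pool 4 (interquartile range 1.07 to 1.40, the others 0.456 to 0.867). The ratios computed here had the same 6 widest arrays over the probes of that table, but over all tested probes only 4 of these were widest (0.818 to 0.841, the next 0.702), with female ivermectin pool 5 at 0.310 and female 1xEMB pool 4 at 0.444. The SD of spike-in ratios was at most 1.728 on these arrays and 1.508 to 1.834 on the others. It was taken between the medians of different spike-in probes, not within a probe. It therefore cannot decide on a fault of labelling, hybridisation or scanning. Random noise is argued against by the median correlation of 0.5041 between the deviations of these arrays from group means (others 0.007). Their lying 1 to a slide on 6 slides argues against 1 bad slide. The spread of the authors' values was wider on ivermectin (mean 0.941) than on control feed (0.618; permutation p within sexes 0.00247, 100000 resamples), but this test was chosen once 5 of the 6 arrays were seen to be ivermectin pools, so it restates that observation; over all tested probes the means here were 0.647 and 0.536. An effect of the feed stays open, as does a fault of labelling, hybridisation or scanning. RNA quality and development of the lice also stay open and were not tested.

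Regrouping the same pools at random, in 100 splits including the real one, served to judge each count. Where under 5 of the 100 splits gave as many calls, so high a count was taken as rare for that comparison alone, with no correction over the 13 comparisons. With 100 splits no share could pass such a correction, so chance is not excluded by this. This held for the sex difference (1 of 100 splits gave as many calls; highest other 1426 against 2760), for 1xEMB in females (3; 211 against 63), in males (2; 761 against 74) and over both sexes (1; 200 against 943), for 3xEMB in females (1; 5 against 7), in males (1; 22 against 124) and over both sexes (2; 176 against 31), and for ivermectin against 1xEMB (3; 1409 against 7). It did not hold for ivermectin in females (23 splits, 226 against 2), in males (100 splits, 3136 against 0) and over both sexes (7 splits, 2571 against 3). Nor did it hold for the interaction (100 splits, 608 against 0) and for 3xEMB against 1xEMB (100 splits, 405 against 0). Where another split called several times the real count, as in 9 of these comparisons, this points to a structure among the pools, whose nature was not tested.

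Blank spots, which hold no louse probe, stood above background on 8.31% of occasions, against 8.03% for the negative control spots.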
